A study of Homo sapiens with 4 samples.

How the data were processed

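RNA from exosomes, the small vesicles that cells release into their medium, was measured on 4 one-colour Agilent arrays. The exosomes came from the supernatant of A549 cells, a human lung adenocarcinoma line, kept at 1% oxygen (hypoxic) or 20% oxygen (normoxic) for 12 or 24 h. Each combination of oxygen level and time has 1 array. Per the labels' protocols, RNA was extracted with a blood RNA kit followed by globin removal, and Cy3-labelled cRNA was made with Agilent's low-input linear amplification kit. The labels do not give the primer, so whether RNA without a poly(A) tail, such as circRNA, was labelled is not known here.

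The deposited spot intensity values are the processed signals, raw mean signals and local backgrounds of Agilent Feature Extraction 10.7.1.1, per the file headers. The submitters' processing notes name Feature Extraction 9.1 instead, and the values do not settle which was run. Per the file headers, the processed intensity was background-subtracted and detrended, dim spots were given surrogate values, and no normalization between arrays was applied. The deposited flags per spot, also from Feature Extraction per the file headers, mark spots well above background, saturated spots, outliers and control spots. The deposited value table of the whole series holds log2 values, as found by comparison with the scanner files. Its columns correlated with the log2 processed signal at r of 0.9998 or more across 138395 probes, and the column medians were 1.79 on all 4 arrays, as quantile normalization between arrays gives. How the authors made it is not given in the sources used here.

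Outlier-flagged spots were left out, the log2 processed signals of the spots of a probe were averaged, and control spots stayed out of the main fit. Only 34.1% of probes were well above background on at least 2 arrays, so each array was scaled to the 75th percentile of the 37254 probes well above background on all 4 arrays, and every level below is a log2 value relative to it. No spot was saturated. Probes well above background on at least 2 arrays were tested, which left 47193 of 138405 probes. Differences between hypoxic and normoxic and between 24 h and 12 h were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the tested probes and an adjusted p under 0.05 as the threshold. The fit leaves 1 residual degree of freedom, the disagreement of the hypoxia difference between the times, which eBayes pooled over probes with 3.57 prior degrees of freedom. Differences at a single time rest on 1 array per group and have no test. The labels do not say whether the arrays come from separate cultures, so a p-value rests only on the spread between these arrays. That spread includes any true change of the hypoxia difference with time. The 4 arrays lay on 1 slide and were scanned in 1 scan, so slide and scan could not act as a batch.

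The number of arrays limits the precision. Among the 1433 probes printed 10 times and well above background on all arrays, the median SD of log2 signal between spots was 0.16, 0.22, 0.14 and 0.16 on the hypoxic 12 h, normoxic 12 h, hypoxic 24 h and normoxic 24 h arrays. For a probe with 1 spot and such signal, a hypoxia difference therefore carries a spot-to-spot SD of 0.27 at 12 h and 0.21 at 24 h. This covers the spots and not the cultures. It does not cover the tested probes that were not well above background on all arrays.

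The fit was tested on simulated arrays with the 47193 probes, the fitted spread and 200 changed probes. For the hypoxic against normoxic comparison it called 0% of 50 probes changed by 1 on the log2 scale, 0% of 50 changed by 2, 36.0% of 50 changed by 3 and 92.0% of 50 changed by 5, with 6 false calls. The mean estimates were 0.99, 2.03, 3.03 and 4.98. At an unadjusted limma p under 0.05 it found 90% of the probes changed by 1 and 100% of those changed by 2. The adjustment is stricter where few probes change, and in the data 25.2% of tested probes had an unadjusted p under 0.05. The shares called in the simulation therefore do not carry over to these arrays.

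The files give no gene names for the array's own probes: name, description and coordinate fields hold the probe ID or no annotation, and the gene table used here holds no probe IDs. Probes are therefore given by ID and 60-base sequence, without a gene or position. Their IDs fall into series called here A (IDs starting with A_, 37549 probes), L (CUST_H6L, 79404 probes) and C (CUST_H6C, 21442 probes), plus 10 further probes. The labels say that the array holds lncRNA and circRNA without saying which IDs are which. The C series was taken as the circRNA probes, because 7.63% of its probes share their first or last 30 bases with another, as probes across back-splice junctions of 1 gene can, against 0.12% in the L series and 0.02% in the A series. The 28 gene lists fixed before the data were examined could not be matched, except for 2 members, GAPDH and PGK1, which name 4 control probes printed 10 times each. These were fitted together with the tested probes.

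The rule for named probes was also fixed before the data were examined. It ranks probes by the smaller of the 12 h and 24 h hypoxia differences among those with the same sign at both times, well above background on both arrays of the higher condition. Probes past the threshold come first, and otherwise those at least 2-fold different at both times. Time differences were ranked in the same way over the hypoxic and normoxic pairs. Opposite probes were ranked by the 12 h minus the 24 h difference. Without gene names at most 2 probes higher and 2 lower are given per comparison. In the comparison over all probes these are the first of the A series and the first of the L series. The ranking uses the measured log2 values, which for dim arrays are background levels. Where the dimmer array of a pair was not well above background, the difference of that pair is given as a lower bound. It sets the brighter array against the higher of the dim probe's own level and the lowest level among probes well above background on the dimmer array. That lowest level is not a strict detection limit. On the normoxic 12 h array it was -4.00, while CUST_H6C_09959 was not well above background there at -3.63. The bounds, given below as at least, and counts made with them are therefore nominal and not guaranteed minimums.

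Sequence direction was studied in Python 3.11.15 by counting dinucleotides and by searching for stretches of at least 20 bases shared between probes, read as listed, reversed, complemented or both. Pairs of probes that share such a stretch took the place of pairs of circRNA and host gene. The alternatives were quantile, median and cyclic loess normalization, normexp background correction with an offset of 50, other filters on dim probes, the deposited value table, a trended and robust prior, a fit without the other factor, an adjusted p under 0.1, centring of each series, removal of a GC trend, the 75th percentile over every probe and scaling to spike-in probes.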

Results

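The RNA of exosomes released by A549 lung adenocarcinoma cells was profiled after 12 and 24 h under 1% or 20% oxygen. The series asked how the circular RNA content of exosomes differs between hypoxic and normoxic cells. There were 4 arrays, 1 for each oxygen level at each time. The series' design text speaks of 2 independent experiments at each time, while the arrays here are 2 at each time, 1 hypoxic and 1 normoxic. How the experiments relate to these arrays is not known here. No condition had a replicate, so values at a single time carry no replicate error. Of 175899 spots outside the controls, 34.3% were well above background on the hypoxic 12 h array, 33.2% on the normoxic 12 h array, 34.7% on the hypoxic 24 h array and 34.4% on the normoxic 24 h array.

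The RNA of PGK1, the glycolytic enzyme phosphoglycerate kinase, was more abundant in hypoxic than in normoxic exosomes at both times. The control probe Human-PGK1_3 was 4.56-fold higher at 12 h and 8.30-fold higher at 24 h, and Human-PGK1_5 was 4.80-fold and 8.19-fold higher. GAPDH, the glycolytic enzyme often used as a reference gene, was also higher, by 1.83-fold at 12 h and 3.97-fold at 24 h for Human-GAPDH_3 and by 1.89-fold and 3.79-fold for Human-GAPDH_5. Each probe was printed 10 times per array, and the SD between its spots lay between 0.06 and 0.22 on the log2 scale, which covers the spots of an array and not the spread between cultures or preparations. Over both times the mean log2 difference was 2.62 with an SE of 0.30 for Human-PGK1_3 and 2.65 with an SE of 0.28 for Human-PGK1_5. It was 1.43 with an SE of 0.34 for Human-GAPDH_3 and 1.42 with an SE of 0.32 for Human-GAPDH_5. GAPDH and PGK1 were the only 2 of the 23 members of the list of glycolysis and glucose uptake genes that could be matched. None of their 4 probes passed the threshold over all probes in limma, with adjusted p = 0.0675 for both PGK1 probes and adjusted p = 0.0972 and 0.0916 for GAPDH. All 4 passed when adjusted over the list alone, with limma adjusted p = 0.000947 for both PGK1 probes and 0.010 for both GAPDH probes. That adjustment covers only these 4 probes of 2 genes, and 25.2% of all tested probes had an unadjusted limma p under 0.05. At 12 h, 88.4% and 89.1% of tested probes had a smaller difference than Human-GAPDH_3 and Human-GAPDH_5. For Human-PGK1_3 and Human-PGK1_5 it was 98.1% and 98.3%. GAPDH also stood in the list of control genes. Scaling to spike-in probes, chosen after seeing the data, brought all 4 past the threshold over all probes, with limma adjusted p between 0.0348 and 0.0431. Under median scaling and the 75th percentile over every probe the lowest adjusted p was 0.0545. These control probes were run under these scalings only. They were not run with quantile or cyclic loess normalization, normexp, the deposited value table or the GC correction. Nor were they run with other filters, the trended and robust prior, centred series or a fit without the other factor.

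**Figure D1:**
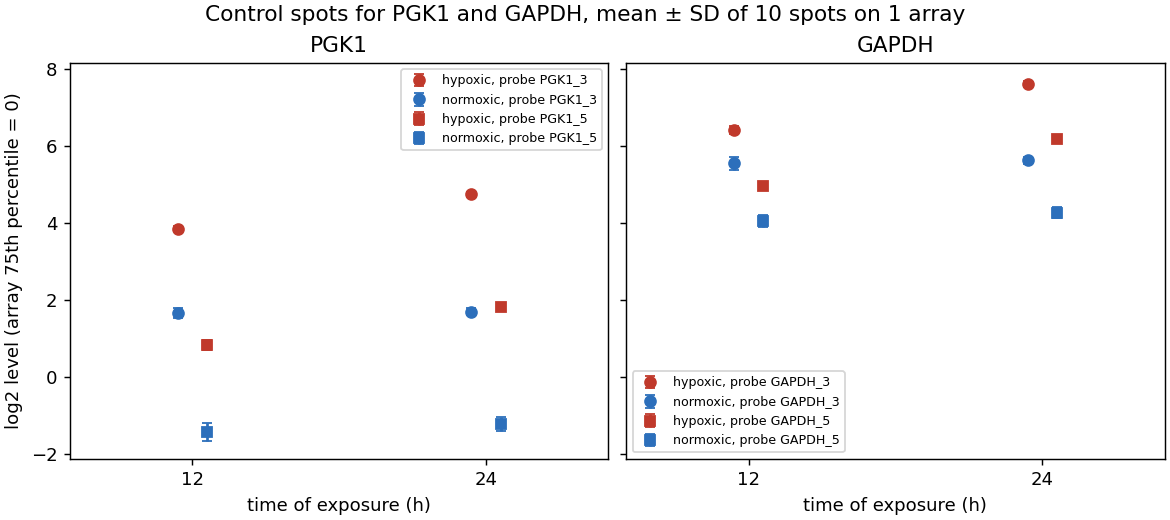
Log2 level relative to the array 75th percentile of the control probes for PGK1 (left) and GAPDH (right) against time in h, with hypoxic arrays in red and normoxic arrays in blue. Points are means and bars the SD of 10 spots on 1 array, and each hypoxic point lies above the normoxic point of the same probe and time, by 2.19 and 3.05 for Human-PGK1_3 and by 0.87 and 1.99 for Human-GAPDH_3.

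The excess of PGK1 and GAPDH in hypoxic exosomes was larger at 24 h than at 12 h for all 4 probes, which read 2 genes on the same 4 arrays. Of the tested probes, 91.2% (for Human-PGK1_5) to 96.2% (for Human-GAPDH_3) had a smaller increase of the hypoxia difference. Between 12 h and 24 h in hypoxia, Human-PGK1_3 was higher at 24 h by 0.89, Human-PGK1_5 by 0.98, Human-GAPDH_3 by 1.19 and Human-GAPDH_5 by 1.22 on the log2 scale. In normoxia the same probes were higher by 0.03, 0.21, 0.08 and 0.21. The design leaves no test of this difference between the times, which enters the SE of the mean differences given above.

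Across all RNAs, many probes differed between hypoxic and normoxic exosomes at both times. At 12 h, 4629 of the 47193 tested probes were at least 2-fold higher in hypoxic exosomes and 2675 at least 2-fold lower. At 24 h, 4010 were at least 2-fold higher and 3414 lower. Of the variation between arrays, 55.0% lay along the oxygen difference, 30.2% along the time difference and 14.9% along their interaction. No condition had a replicate array, so these shares have no error term. Each also holds noise between arrays and preparations, and independent noise alone would give equal shares on average. The shares therefore do not measure the effects of oxygen and time alone. With limma 0 probes passed an adjusted p of 0.05 for the hypoxia difference, with a lowest adjusted p of 0.0677, while 11900 probes (25.2%) had an unadjusted p under 0.05, 5677 of them higher in hypoxic exosomes and 6223 lower. The count of 0 lay close to the threshold, since 5112 probes had an adjusted p under 0.1. It also depended on settings fixed beforehand: 5788 probes passed with a trended and robust prior, 4809 when only probes well above background on all 4 arrays were tested and 4310 with normexp background correction. Scaling to spike-in probes gave 2669 calls.

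The split into higher and lower probes depended on the scaling. At 12 h 63.4% of the probes at least 2-fold different were higher in hypoxic exosomes, and at 24 h 54.0% were. Scaled to the 7 E1A spike-in probes well above background on all arrays, which differ in direction from some of the ERCC control probes, these shares were 92.7% and 74.5%, and the median hypoxia difference of all tested probes moved from -0.07 to 0.39 at 12 h and from -0.04 to 0.16 at 24 h. With normexp background correction the shares were 86.1% and 80.8%, of 1151 and 1219 probes, and with no filter on dim probes the share at 12 h was 46.3%. The labels do not say how the spike-in RNA was added, and all other differences are given relative to the array 75th percentile.

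In the A series the probe first in the ranking upwards was A_33_P3295358 (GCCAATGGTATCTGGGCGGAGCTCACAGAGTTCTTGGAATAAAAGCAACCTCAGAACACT), 28.9-fold higher in hypoxic exosomes at 24 h and at least 11.8-fold higher at 12 h, where the normoxic array was not well above background. In the L series it was CUST_H6L_04520 (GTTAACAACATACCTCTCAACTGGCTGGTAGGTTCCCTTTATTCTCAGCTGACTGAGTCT), well above background on all 4 arrays and 15.9-fold higher at 12 h and 18.2-fold higher at 24 h, with a mean log2 difference of 4.09 and an SE of 0.22. The first downwards were A_23_P133665 (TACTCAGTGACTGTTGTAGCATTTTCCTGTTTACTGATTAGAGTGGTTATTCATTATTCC), 6.48-fold lower in hypoxic exosomes at 12 h and at least 7.05-fold lower at 24 h, where the hypoxic array was not well above background, and CUST_H6L_30168 (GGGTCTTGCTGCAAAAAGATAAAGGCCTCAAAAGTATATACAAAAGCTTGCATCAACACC), which was at least 2.79-fold lower at 12 h and at least 2.17-fold lower at 24 h in hypoxic exosomes, where it was not well above background on either array. None of these 4 probes passed the threshold, each having an adjusted p of 0.0677 in limma, and they were chosen for size and for the same sign at both times.

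The 12 h and 24 h pairs, which share no array, gave similar hypoxia differences. Across the 47193 probes, Pearson's r between the 12 h and 24 h differences was 0.58 and Spearman's rho was 0.54, where probes are not independent replicates. In the A series r was 0.64, in the L series 0.56 and in the C series 0.39. At least 2-fold higher at both times were 2197 probes, against 393 for independent lists, and at least 2-fold lower at both times were 1158, against 194. The match rose with the signal, from an r of 0.43 in the dimmest of 5 equal bins of tested probes to 0.78 in the brightest. Among the 1689 tested probes with 10 spots r was 0.79.

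**Figure D2:**
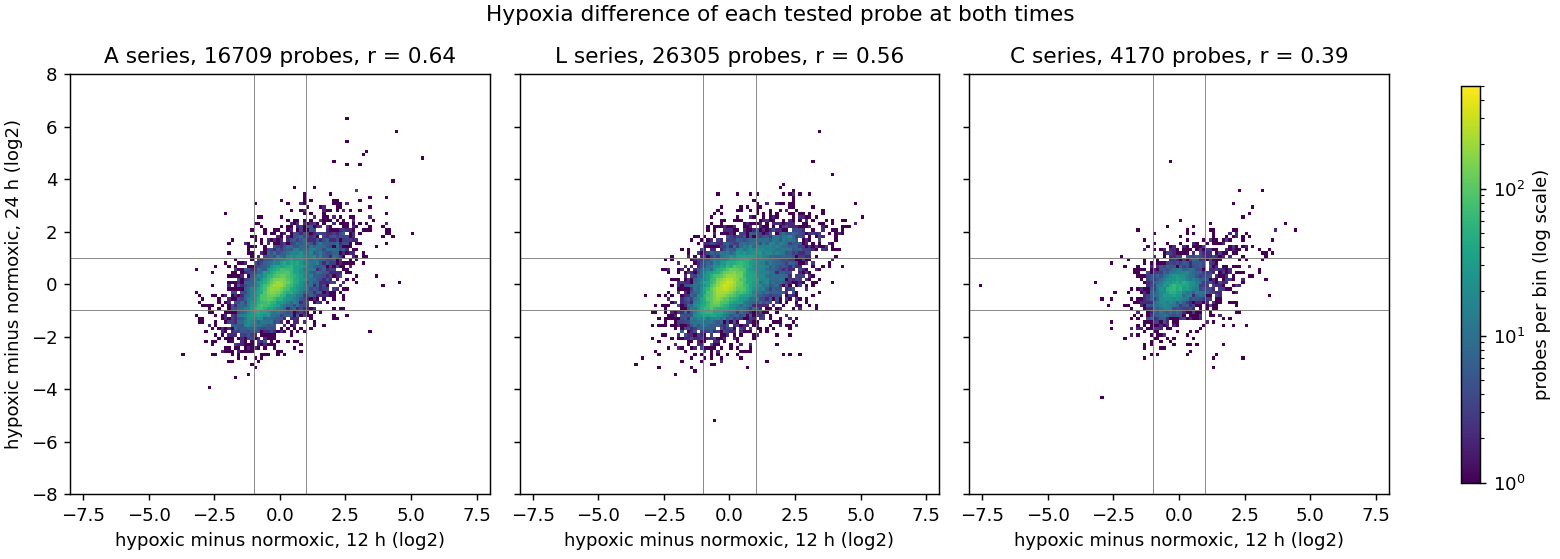
Hypoxic minus normoxic log2 difference at 12 h (horizontal axis) against 24 h (vertical axis) for the tested probes of the A, L and C series, coloured by the number of probes per bin on a log scale, with grey lines at a 2-fold difference. The cloud follows the diagonal most closely in the A series (r = 0.64) and least in the C series (r = 0.39).

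The C series was taken as the probes for circRNA, which the series title is about. Its sequences ran in reverse of the other series, as described below, so which RNA gave its signal is not known here. Among its 4170 tested probes, 105 were at least 2-fold higher in hypoxic exosomes at both times, against 17.9 for independent lists, and 54 at least 2-fold lower at both times, against 15.6. The first upwards were CUST_H6C_18954 (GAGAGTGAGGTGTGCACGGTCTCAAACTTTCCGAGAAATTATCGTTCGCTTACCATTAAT), at least 2.87-fold higher at 12 h and 3.48-fold at 24 h, and CUST_H6C_11418 (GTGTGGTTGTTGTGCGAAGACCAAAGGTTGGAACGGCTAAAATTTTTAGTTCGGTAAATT), at least 2.25-fold higher in hypoxic exosomes at 12 h and 5.18-fold at 24 h. The first downwards were CUST_H6C_07223 (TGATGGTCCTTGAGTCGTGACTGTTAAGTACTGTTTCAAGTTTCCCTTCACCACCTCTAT), at least 6.62-fold lower at 12 h and 6.0-fold at 24 h, and CUST_H6C_17701 (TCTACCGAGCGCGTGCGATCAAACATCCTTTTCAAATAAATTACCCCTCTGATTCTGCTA), at least 1.57-fold lower at 12 h and 2.16-fold at 24 h. All 4 were not well above background on either array of the dimmer condition, and none passed the threshold, with an adjusted p of 0.0677 each in limma. No C-series probe passed it, over all probes or adjusted over the C series alone, where the lowest adjusted p was 0.109, and 799 (19.2%) had an unadjusted p under 0.05. Over all probes, 273 C-series probes passed with a trended and robust prior, 226 among probes well above background on all arrays, 199 with normexp and 123 with spike-in scaling. Adjusted over the C series alone, 155, 90, 95 and 0 passed under the same settings.

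The C-series sequences ran in the opposite direction to those of the other series. In the A and L series the dinucleotide CG was rare, at 0.32 and 0.22 of its expected count, as in human transcripts in general, and GC stood at 0.97 and 0.94. In the C series CG stood at 1.01 and GC at 0.34. Read in reverse, without complementing, 1938 of the 21442 C-series probes (9.04%) shared at least 20 bases with an A-series or L-series probe, against 17 as listed. Complemented without reversing, 204 C-series probes matched, and 10 when both reversed and complemented. For L-series probes against the A series, 1061 matched as listed, 22 in reverse, 16 complemented and 140 both reversed and complemented. The values of the C series are therefore given as probe signals, without stating which RNA they came from.

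**Figure D3:**
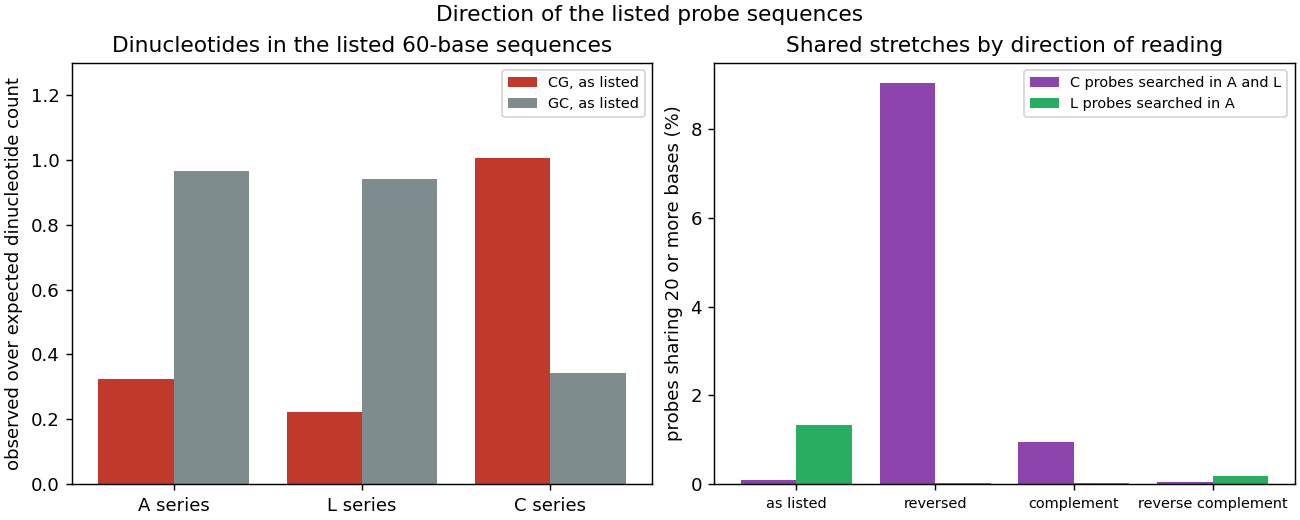
Left, observed over expected count of the dinucleotides CG and GC in the listed sequences of the A, L and C series. Right, percent of C-series probes (searched in A and L) and of L-series probes (searched in A) that share at least 20 bases, by direction of reading. Most C-series matches lie in the reversed reading (9.04%), with fewer in the complement (0.95%). Most L-series matches lie in the listed reading (1.34%), with fewer in the reverse complement (0.18%).

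Pairs of probes that share a stretch of sequence were compared in place of circRNAs and their host genes. For 372 pairs of a C-series probe and an A-series or L-series probe that holds its reversed stretch, both tested, the rank correlation of the hypoxia difference was 0.19 (95% interval 0.08 to 0.29 over 1000 resamples of the pairs). It was 0.32 (0.18 to 0.45) for the 186 pairs sharing 20 to 29 bases and 0.06 (-0.07 to 0.20) for the 186 sharing 30 or more. For 700 pairs of an L-series and an A-series probe it was 0.84 (0.81 to 0.87). These are correlations across probe pairs, which are not independent replicates.

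The share of probes well above background differed between the series and little between the conditions. In the C series it was 19.1% on the hypoxic and 18.8% on the normoxic array at 12 h, and 18.0% and 18.5% at 24 h. In the L series it was 32.1% and 30.5% at 12 h and 32.4% and 31.6% at 24 h, and in the A series 42.5% and 41.6% at 12 h and 43.2% and 43.4% at 24 h. The median hypoxia difference of the tested C-series probes was -0.10 at 12 h and -0.14 at 24 h, against -0.08 and -0.06 in the A series and -0.05 and -0.02 in the L series. No test of these shifts was made.

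The time of exposure moved fewer probes in the same direction than oxygen did. Between 12 h and 24 h, 3384 probes were at least 2-fold higher and 2315 at least 2-fold lower in normoxic exosomes, and 1486 and 1406 in hypoxic exosomes. The larger normoxic counts rest on 1 array per time. The normoxic 12 h array had the largest SD between spots (0.22) and the fewest probes well above background (43886). The counts therefore do not show that time changed normoxic exosomes more. In both conditions 590 were higher, against 106.6 for independent lists, and 302 lower, against 69.0, and r across probes was 0.35. The 2-fold counts for time were made only relative to the array 75th percentile. On that scale the mean E1A spike-in level was 2.06 at 12 h and 1.48 at 24 h in normoxic samples, and 1.61 and 1.27 in hypoxic samples. How the time counts and their comparison with oxygen depend on the scaling was therefore not tested. Highest in rank at 24 h was CUST_H6L_31398 (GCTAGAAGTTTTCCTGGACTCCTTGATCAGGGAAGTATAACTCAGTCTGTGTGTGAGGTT), at least 2.69-fold higher than at 12 h in hypoxic and 1.72-fold in normoxic exosomes. Next was CUST_H6L_66420 (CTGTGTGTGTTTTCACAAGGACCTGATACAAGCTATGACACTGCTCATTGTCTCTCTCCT), at least 5.94-fold higher in hypoxic and 1.45-fold in normoxic exosomes. Lowest were CUST_H6C_07281 (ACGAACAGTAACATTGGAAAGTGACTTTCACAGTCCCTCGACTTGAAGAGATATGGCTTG), at least 1.83-fold lower at 24 h in hypoxic and 5.97-fold in normoxic exosomes, and CUST_H6L_55243 (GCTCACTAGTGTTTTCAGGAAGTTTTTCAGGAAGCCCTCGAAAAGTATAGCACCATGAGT), 6.67-fold lower at 24 h in normoxic exosomes and at least 5.61-fold lower in hypoxic exosomes, where the 24 h array was not well above background. No probe passed the limma threshold for time, where the lowest adjusted p was 0.289 and 6600 probes (14.0%) had an unadjusted p under 0.05. With a trended and robust prior 302 passed, and with normexp 355.

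Of the 47193 tested probes, 14710 (31.2%) had hypoxia differences of opposite sign at the 2 times, and few of these were 2-fold or more at both. At least 2-fold and opposite were 138 probes, against 562 for independent lists, of which 96 were higher in hypoxic exosomes at 12 h and lower at 24 h and 42 the reverse. Only 16 of the 138 were well above background on all 4 arrays, none was among the probes with 10 spots, and 61 stayed at 2-fold or more at both times with dim arrays counted as bounds. By the rule for named probes, CUST_H6L_70562 was at least 3.91-fold higher in hypoxic exosomes at 12 h and at least 2.30-fold lower at 24 h, and A_21_P0009582 at least 3.25-fold higher and 3.43-fold lower. In the other direction A_23_P157793 was at least 1.89-fold lower at 12 h and at least 1.95-fold higher at 24 h. CUST_H6C_09959 was 4.17-fold higher at 24 h and not well above background on either array at 12 h, so it has no measured difference there. The difference between the times has no test in this design.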

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

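All tests of explanations in this part were chosen after the results were seen. The hypoxia differences of 138 probes were at least 2-fold and opposite at 12 h and 24 h, which drew attention because the single hypoxic and normoxic pair of each time gave opposite directions. The difference was not tested. CUST_H6L_70562 was at least 3.91-fold higher in hypoxic exosomes at 12 h and at least 2.30-fold lower at 24 h, A_21_P0009582 at least 3.25-fold higher and 3.43-fold lower, and A_23_P157793 at least 1.89-fold lower and at least 1.95-fold higher. Each has 1 spot per array, and the bounds mark times with an array not well above background. With such arrays counted as bounds, 61 of the 138 stayed at 2-fold or more at both times.

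The probe sequences, which no comparison of signals uses, held a pattern of their own: 1938 C-series probes shared at least 20 bases with an A-series or L-series probe when read in reverse, against 22 of the 79404 L-series probes read in reverse against the A series. A reversed listing alone is argued against by probes not well above background on any array, where the effect of an A at each position of C-series probes followed that in the L series as listed (r = 0.89) and not turned round (r = -0.44, at most -0.33 in 100 resamples). Binding of the linear RNA that holds the reversed stretch is argued against as the main source by the hypoxia differences of the pairs. Their rank correlation was 0.19 (0.08 to 0.29), below the 0.84 (0.81 to 0.87) of L-series and A-series pairs. The pairs were not matched on level, and C-series differences matched less between the times (r = 0.39 against 0.56 in the L series and 0.64 in the A series). Part of the gap can come from this, so it does not measure binding alone. Split by length, the rank correlation of the C-series pairs was 0.32 (0.18 to 0.45) for 20 to 29 shared bases. For 30 or more it was 0.06 (-0.07 to 0.20), while the L-series and A-series pairs gave 0.83 and 0.86. The correlation thus did not rise with the length shared, which argues against such binding as the main source where 30 or more bases were shared. A smaller part from linear RNA stays open. The effect of an A goes with C-series probes built as listed, and so in reverse of the other series. That such probes bind other RNA stays open as a candidate explanation, and whether circRNAs gave any of their signal was not tested.

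The C-series hypoxia differences matched less between the times (r = 0.39) than those of the other series. Dimmer signal is argued against as the whole cause, since 100 draws of as many A-series and L-series probes with 1 spot and the same levels gave r between 0.524 and 0.603. At least 2-fold different in the same direction at both times were 159 C-series probes, against 276 to 358 in the draws. The probes' direction of reading is a candidate explanation, which the arrays do not test.

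The hypoxia difference shared by 12 h and 24 h (r = 0.577) was set against a trend with intensity between arrays. Cyclic loess, which moved the differences by a median of 0.05 at 12 h and 0.07 at 24 h, left r at 0.5762, so such a trend is argued against as the cause. A biological effect of oxygen stays open as a hypothesis, beside any other difference in how the hypoxic and normoxic samples were handled at both times, which the design cannot tell from oxygen.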

How the results depend on the processing

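Cyclic loess, the percentile over every probe, the GC correction and the spike-in scaling were chosen after seeing the data. For the hypoxia difference, 0 probes passed in the analysis as reported and under 9 alternatives. Calls appeared with normexp (4310 probes, 199 of the C series, 95 adjusted over the C series alone), with probes well above background on all arrays (4809, 226 and 90), with a trended and robust prior (5788, 273 and 155), at an adjusted p under 0.1 (5112, 263 and 0) and with spike-in scaling (2669, 123 and 0). For time, calls appeared with normexp (355) and with the trended and robust prior (302). The cause of these calls was not tested. Probes at least 2-fold different numbered 7304 at 12 h and 7424 at 24 h. They numbered 20610 and about 20450 without a filter on dim probes, 1151 and 1219 with normexp, and 3762 and 4286 among probes well above background on all arrays. Opposite probes numbered 1327, 1 and 16 under the same settings, and r between the times was 0.3053, 0.7236 and 0.6418. Without the filter, the rank correlation of C-series pairs was 0.059 and the median difference of the C series from the A series moved from -0.05 to -0.0073. Normexp with an offset of 50 shrinks the differences of dim probes by construction, and leaving out the filter brings in probes that no array measured well above background. The 12 named hypoxia and time probes and the 4 control probes passed the alternative's threshold in 37 of 169 tests. None changed sign, which shows little, since most were chosen for large differences of 1 sign. The filter on signal over background left the smallest share in the C series, where 19.4% of probes were tested, against 33.1% in the L series and 44.5% in the A series. No paired analysis was possible because the groups share only replicate number 1, so replicate numbers give no block; the time term of the analysis as reported already takes the hypoxia difference within each time, and without it 0 probes passed, with a lowest adjusted p of 0.183 against 0.0677. Averaging probes of a feature and a slide or scan block were not run, since the files name no features beyond single probes and give 1 slide, and of the gene lists only the 2 members named by control probes were tested.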

Other observations

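Control probes named for mouse and rat genes lay outside the report's comparisons. Rat-PGK1_5 was higher in hypoxic exosomes by 2.12 on the log2 scale at 12 h and 2.96 at 24 h, Mouse-PGK1_5 by 1.72 and 2.86, and Rat-GAPDH_5 by 0.97 and 1.97, close to the human probes of the same names. Mouse-GAPDH_3, Mouse-GAPDH_5 and Rat-GAPDH_3 differed by -0.18, 0.14 and -0.41 at 12 h and by 0.27, -0.18 and -0.26 at 24 h. These 6 were well above background on all 4 arrays, and Mouse-PGK1_3 and Rat-PGK1_3 on none.

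Of the 7 E1A spike-in probes well above background on all arrays, 6 were lower in hypoxic than in normoxic samples at both times relative to the array 75th percentile. Their mean difference was -0.45 ± 0.30 at 12 h and -0.21 ± 0.15 at 24 h (SD over the 7 probes). The probe that was higher, (+)E1A_r60_3, differed by 0.21 and 0.09. The 3 control probes named ERCC that were well above background on all arrays did not share one direction: ERCC-00028_121 differed by 0.29 at 12 h and 0.22 at 24 h, ERCC-00062_278 by 0.08 and 0.49, and ERCC-00171_229 by -0.07 and -1.06. ERCC-00012_90, well above background on 3 arrays, differed by 0.49 and 0.67. Relative to the E1A probes, Human-PGK1_3 was higher in hypoxic exosomes by 2.64 at 12 h and 3.26 at 24 h.

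The spread of the hypoxia difference was larger than the spot-to-spot noise. Among probes with 10 spots that were well above background on all arrays, the SD over probes was 0.60 at 12 h and 0.62 at 24 h, against 0.08 and 0.07 from the spots. This compares arrays with spots and not cultures with cultures.

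The first principal component held 66.9% of the variation between arrays. Its values were -117 for normoxic 12 h, -22.7 for normoxic 24 h, 37.5 for hypoxic 12 h and 103 for hypoxic 24 h.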
